A study of Homo sapiens with 2 samples.

How the data were processed

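Total RNA of transfected IGROV1-R10 cells was converted to biotin-labelled single-strand cDNA and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols, with 1 array per group (miR-491-5p or control miRNA, as stated in the transfection label). The deposited values are log2 signals per transcript cluster (called probe set here), 1 column per array with 2 decimals. They were made with RMA, per the submitters' processing notes. The software version and any background or GC correction are not given in the sources used here, and the log base is taken from RMA. Deposited log2 values ran from 2.53 to 19.22 on the miR-491-5p array (median 5.51) and from 2.58 to 19.18 on the control array (median 5.59). Sorted values of the 2 arrays differed by up to 0.14, so the columns were not at identical quantiles. The top values exceed the log2 range that raw scanner intensities usually span, so a rescaling that stretches differences is possible, and folds here are powers of 2 of the deposited differences. Scanner intensities were not used here, so background correction and probe-level normalization could not be varied, and signal over background is unknown. With 1 array per group, their number limits the precision: no spread between cultures exists, no gene was tested between the groups and no p-value is given.

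Of 67528 probe sets, 23781 carried 1 gene symbol in GEO's platform annotation, 1543 carried several and 42204 were unnamed here. Of the probe sets with 1 symbol, 21497 matched a RefSeq gene by Entrez ID, which changed 0 symbols, and the other 2284 kept the annotation's name. Probe sets with several symbols or none stayed out of the gene comparison. Each of 22465 genes took the probe set with the highest mean of the 2 arrays. For 277 genes with more than 1 probe set above the filter, 10 had differences spread over 0.5 or more (log2). Genes were kept when the higher of the 2 values was at or above 5.55, the median of all values of both arrays, which left 14373 genes, 11578 of them protein-coding. The array cannot tell near-identical gene copies apart.

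The difference was the miR-491-5p value minus the control value as deposited, with no further scaling, and a size of 1 (2-fold) was counted. Named genes were the 15 largest differences in each direction above the filter, ties included, leaving out uncharacterised loci, small RNAs and pseudogenes. To these were added all earlier reported targets, up to 4 members with the largest differences of each list, and FOCAD and MIR491. The 38 gene lists, the filter, the thresholds and the naming rule were fixed before the data were examined. Older symbols in the lists were updated through RefSeq synonyms. For the 35 lists with at least 3 members above the filter, the median difference was ranked among medians of 10000 random gene sets of the same size, matched on mean signal in 20 bins. A list stood apart in the outer 0.5 percentiles on either side. These percentiles describe how a list ranks on these 2 arrays and are not tests across cultures.

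The procedure was tested on simulated data with the spread of differences seen between these arrays (SD 0.193 from the median absolute deviation) over 14373 genes. Of 100 genes lowered and 100 raised by 1.5 (log2), 100 and 96 were found past 2-fold, with 0 unchanged genes called. All 20 simulated lists of 15 genes lowered by 0.4 fell below the lower bound, and 0 of 20 unshifted lists passed either bound. The simulated differences were drawn independently from a normal distribution whose SD came from these 2 arrays, not from replicates. Few false calls were therefore to be expected, and the simulation does not measure false calls between cultures. Alternatives were median centring, a loess correction on signal (span 0.3), no filter, a filter on both arrays, the mean of a gene's probe sets, 1.5-fold and 3-fold thresholds, and unmatched random sets. The planned comparison of genes with and without seed-matched sites was not run, because transcript sequences were not used here. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.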

Results

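The series profiled total RNA from IGROV1-R10, a cisplatin-resistant derivative of the human ovarian carcinoma cell line IGROV1, on 2 whole-transcript expression arrays. One array held RNA from cells transfected with a miR-491-5p duplex, a synthetic double-stranded form of a small RNA that represses messenger RNAs with matching sites. The other held RNA from cells transfected with a control miRNA duplex. Both duplexes were given at 20 nM, 24 hours after seeding, and 100 ng of RNA was labelled per array. The comparison asks which transcripts differ in abundance when these cells receive miR-491-5p. Each group had 1 array and no replicates, so no difference below has an error between cultures or a p-value. All values are log2 signals, all differences are the miR-491-5p array minus the control array, and "higher" and "lower" describe these 2 arrays alone.

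Far more genes were lower than higher on the miR-491-5p array. Of 14373 genes above the signal filter, 109 (0.758%) were at least 2-fold lower and 7 (0.0487%) at least 2-fold higher. After centring the differences on their median, 81 were lower and 13 higher, and after a loess correction 76 and 13. The median difference over these genes was -0.07, and the middle 95% of them lay between -0.68 and 0.37. The 2 arrays correlated at r = 0.995 across these genes, which are not independent replicates. The lowest gene was TRNP1, a nuclear protein known from neural progenitors, at 9.02 against 11.19 (4.50-fold lower). CDH5, the adhesion molecule VE-cadherin, followed at 11.10 against 13.23 (4.38-fold lower), and LRRN4, a leucine-rich repeat membrane protein, stood at 11.28 against 13.26 (3.94-fold lower). TNF, the inflammatory cytokine, was 3.81-fold lower, and its probe sets on the alternative haplotypes of its locus differed by -1.93 to -2.02.

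The other genes with the largest negative differences had varied known functions. LYPLA2, an acyl-protein thioesterase, was 3.78-fold lower. A pseudogene of it, LYPLA2P2, differed by -1.51, and the probes may not separate the pair. MYL9, a regulatory light chain of myosin, went from 14.43 on the control array to 12.58 on the miR-491-5p array, and CARM1, an arginine methyltransferase and transcriptional coactivator, from 13.40 to 11.57. EMP1, an epithelial membrane protein, and ANKRD52, a regulatory subunit of protein phosphatase 6, each differed by -1.78. SAMD4B and RAVER1, both RNA-binding proteins, differed by -1.76 and -1.65. SLC25A23, a mitochondrial carrier, differed by -1.71, the membrane protein TM4SF1 by -1.67 and JMJD8 by -1.65. EGFR, the epidermal growth factor receptor, and ETV4, an ETS transcription factor induced by ERK signalling, were also among these 16 genes.

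Positive differences were smaller. UHMK1, a serine/threonine kinase, was the highest at 12.98 against 11.40 (2.99-fold higher). TP53INP1, a stress-induced p53 target that promotes cell death and autophagy, was 2.60-fold higher, the desmosomal cadherin DSC2 2.19-fold, TMCC3 2.10-fold, SESN3, a sestrin that restrains mTORC1, 2.03-fold, and ARHGAP19 2.01-fold. The remaining gene past 2-fold was the miRNA locus MIR569 (difference 1.02), which lies outside the naming rule. Just under 2-fold were the mitotic kinesin KIF4A (0.98), the kinase HIPK1 (0.97), MAP2K6, which activates p38 (0.96), NARS2 (0.96), MNAT1 (0.95), YWHAB (0.94), ADGRE5 (0.92), NEB (0.90) and the desmosomal protein PKP2 (0.89). The probe set for the miRNA's own locus, MIR491, read 4.10 against 3.84, below the filter, and its host gene FOCAD read 10.39 on both arrays. These probes target precursor and host transcripts, so they do not check the delivered duplex.

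**Figure D1:**
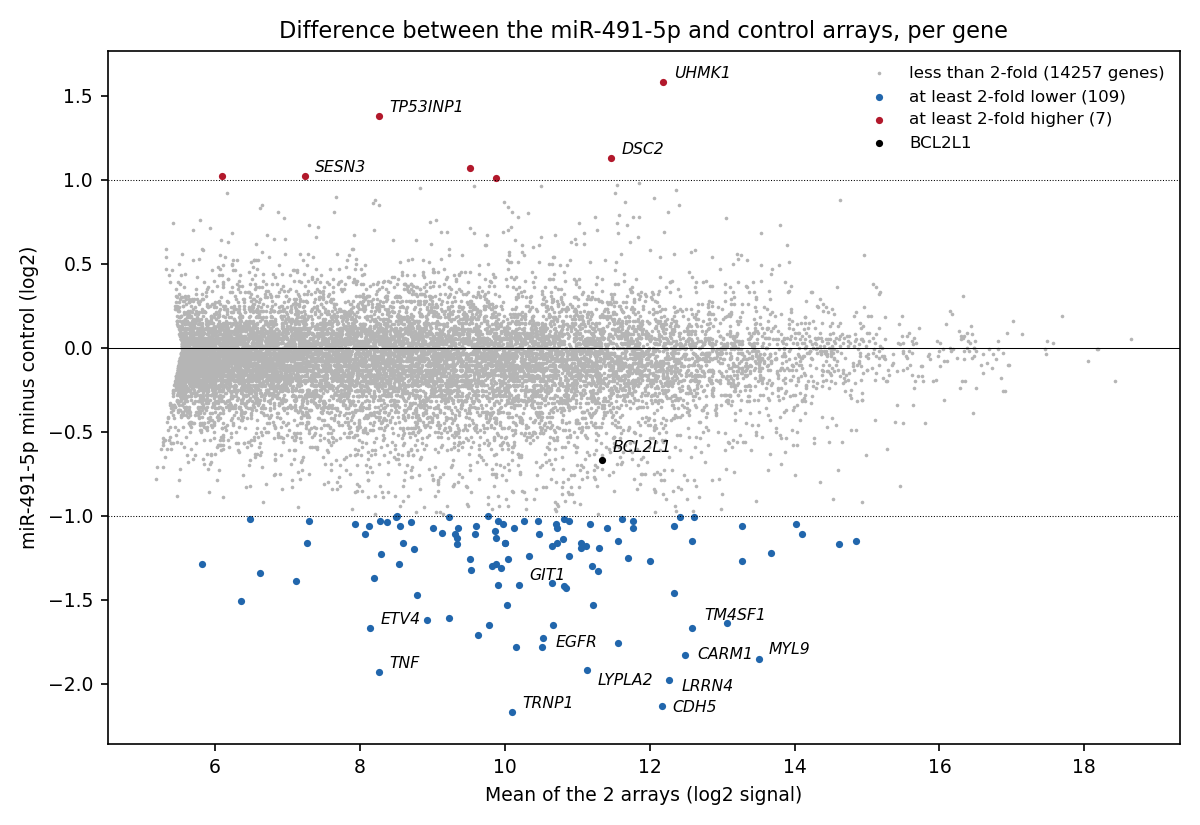
Each point is 1 of 14373 genes. The x axis is the mean log2 signal of the 2 arrays and the y axis the miR-491-5p minus control difference (log2); dotted lines mark 2-fold. Of the 109 blue genes, 4.59% lie in the dimmest tertile of genes, and 7 red genes lie above the upper line; BCL2L1 (black) is at -0.67.

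All 6 measured members above the filter among 9 genes named as miR-491-5p targets in earlier work were lower on the miR-491-5p array. EGFR was 3.32-fold lower (9.67 against 11.40), and GIT1, a GTPase-activating scaffold protein of focal adhesions, was 2.66-fold lower (9.49 against 10.90). The other 4 did not reach 2-fold. SMAD3, a TGF-beta signal transducer, was 1.60-fold lower, BCL2L1, which encodes the anti-apoptotic protein BCL-XL, 1.59-fold lower (11.01 against 11.68), IGF2BP1, an mRNA-binding protein, differed by -0.52 and KDM4B, a histone demethylase, by -0.44. The list median was -0.68, below all of 10000 random gene sets matched on signal, whose middle 95% lay between -0.31 and 0.11. MMP9 (5.28 against 5.43) and CDK6 (5.03 against 5.28) were below the filter, and FOXP4 was not analysed here. The list was compiled from memory of the literature before the data were examined, and it includes targets described in ovarian carcinoma cells, so it is not fully independent of this system.

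Genes that report ERK signalling downstream of growth factor receptors were lower as a group. Of 17 members, 14 had a negative difference, 9 were at least 1.5-fold lower and 2 at least 2-fold lower. The list median was -0.63, below all 10000 matched random sets, against a random median of -0.07. ETV4 was 3.18-fold lower and FOSL1, an AP-1 subunit, 2.23-fold lower. The ERK phosphatase DUSP6 differed by -0.89 and the feedback inhibitor SPRY4 by -0.86. EPHA4 (0.81), EGR1 (0.32) and CCND1 (0.17) went the other way. Among the 7 ERBB receptors and ligands above the filter, EGFR and the ligand EREG (2.08-fold lower, but at -0.99 after median centring) were past 2-fold, HBEGF differed by -0.53 and ERBB3 by 0.45. Their median of -0.20 ranked at percentile 6.96, inside the bounds set for a list to stand apart (the outer 0.5 percentiles on either side). Intracellular RAS and MAPK pathway members ranked at percentile 62.0 (SHC1 -0.69, ARAF -0.46), and PI3K and mTOR members at 34.1 (RPTOR -0.49).

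NF-κB targets and cytokines were the third list below all 10000 matched random sets, with a median of -0.50. All 10 members above the filter had negative differences. However, CCL2 (5.32 against 5.79), IL6 (5.46 against 5.84) and CXCL2 (5.36 against 5.63) reached the filter on the control array only, which fixed their sign. With both arrays above the filter, 7 members had a median of -0.60, at percentile 0.03. TNF and LIF, an IL-6 family cytokine (2.45-fold lower), were past 2-fold, and TNFAIP3 and NFKB2 each differed by -0.60. RELB differed by -0.36, and NFKBIA (11.05 against 11.20) differed least of the list, by -0.15. A further pair of lists stood apart by small amounts on the high side: 4 of 21 G2/M genes and 4 of 15 respiratory chain genes were below 0. The G2/M median was 0.06 (percentile 99.7, KIF20A 0.50, AURKA 0.20), and the respiratory chain median 0.09 (percentile 99.7, COX4I1 0.28, SDHC 0.27). After median centring these medians were 0.13 and 0.16. No member of either list reached 1.5-fold. In all, 5 of 35 lists stood apart. By chance 0.35 would if list members varied as independently as randomly drawn genes, which co-regulated members need not do. The excess over 0.35 therefore does not measure chance differences between cultures.

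Apoptosis genes did not stand apart as lists. Among 7 pro-apoptotic BH3-only genes, BIK was at 0.51, BCL2L11, which encodes BIM, at 0.41 and BMF at 0.38, whereas PMAIP1 was at -0.31. The list median was 0.00 (percentile 78.5). A second BCL2L11 probe set read 0.84. Of the anti-apoptotic family, MCL1 (-0.13) and BCL2L2 (-0.10) passed the filter beside BCL2L1, and their median was at percentile 32.6. Caspases and their regulators ranked at percentile 38.4, with BAX at -0.42 and BOK at -0.40. Among 17 p53 targets, TP53INP1 was at least 2-fold higher and the death receptor FAS 2.19-fold lower, with PLK3 at -0.75 and DDB2 at 0.53 (percentile 4.75).

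Stress, lineage and repair lists lay inside the percentile bounds. The ATF4 stress list ranked at percentile 0.71, just inside the bound, with CHAC1, a glutathione-degrading enzyme, 2.07-fold lower (-0.98 after median centring), SLC3A2 at -0.66 and DDIT3 at -0.59. The mesenchymal list ranked at percentile 0.92, with the transcription factor SNAI1 2.03-fold lower (-0.95 after median centring), ITGA5 at -0.68 and VIM at -0.33. Epithelial genes ranked at percentile 9.11 and went both ways, with KRT18 at -0.60 and CDH1 at 0.50. TGF-beta targets ranked at percentile 3.80 (SMAD7 -0.41), YAP targets at 6.97 (CCN1 -0.65, LATS2 0.72) and chaperones of the unfolded protein response at 13.9 (HERPUD1 -0.39). Platinum transport and detoxification genes, considered because this line resists cisplatin, ranked at 21.2 (ABCC2 -0.48), nucleotide excision repair at 46.3 (DDB2 0.53) and homologous recombination at 50.1 (XRCC2 -0.43).

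Lists for cell cycle entry and general metabolism also lay inside the bounds. G1/S genes ranked at percentile 57.9 (MCM2 -0.84, TYMS 0.55) and G1 cyclins, CDKs and inhibitors at 92.6 (CDK4 -0.62, CDKN1B 0.49). Immediate early genes ranked at 53.9, with FOS at 0.59 and KLF6 at -0.72. The remaining percentiles were 57.0 for hypoxia and glycolysis (SLC2A1 -0.63), 65.0 for cholesterol synthesis (CYP51A1 -0.31), 67.4 for NRF2 targets (TXNRD1 -0.78), 56.3 for WNT targets (MYC -0.54), 96.8 for lysosome and autophagy (GABARAPL1 0.50), 42.7 for the miRNA machinery (TNRC6C 0.64), 29.6 for ribosomal proteins (RPS19 -0.37), 69.8 for reference genes (B2M 0.58) and 91.4 for ovarian carcinoma markers (MECOM 0.45, PAX8 -0.18).

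Interferon-stimulated genes, which respond to foreign double-stranded RNA, had a median difference of -0.05 (percentile 62.5). Both cultures received a duplex and no untransfected array exists, so a response shared by both would cancel in this difference. Of 23 measured, 8 passed the filter, and the largest difference among these 8 was OAS3 at 0.22. Below the filter, IFNB1 read 3.98 against 4.60 and IFIT1 5.26 against 5.39. Markers of other cell types were mostly under the filter. Fibroblast markers had 2 of 9 above it (COL1A1 -0.07, THY1 -0.09), melanocyte and neural markers 2 of 6 (SOX2 -0.17, GFAP -0.17) and leukocyte markers 3 of 11 (CD3E -0.35, percentile 5.83). Endothelial markers had 2 of 9, CDH5 and CLDN5 (-0.25), while PECAM1 (4.51 against 4.35) and VWF (5.07 against 5.20) were not above it.

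**Figure D2:**
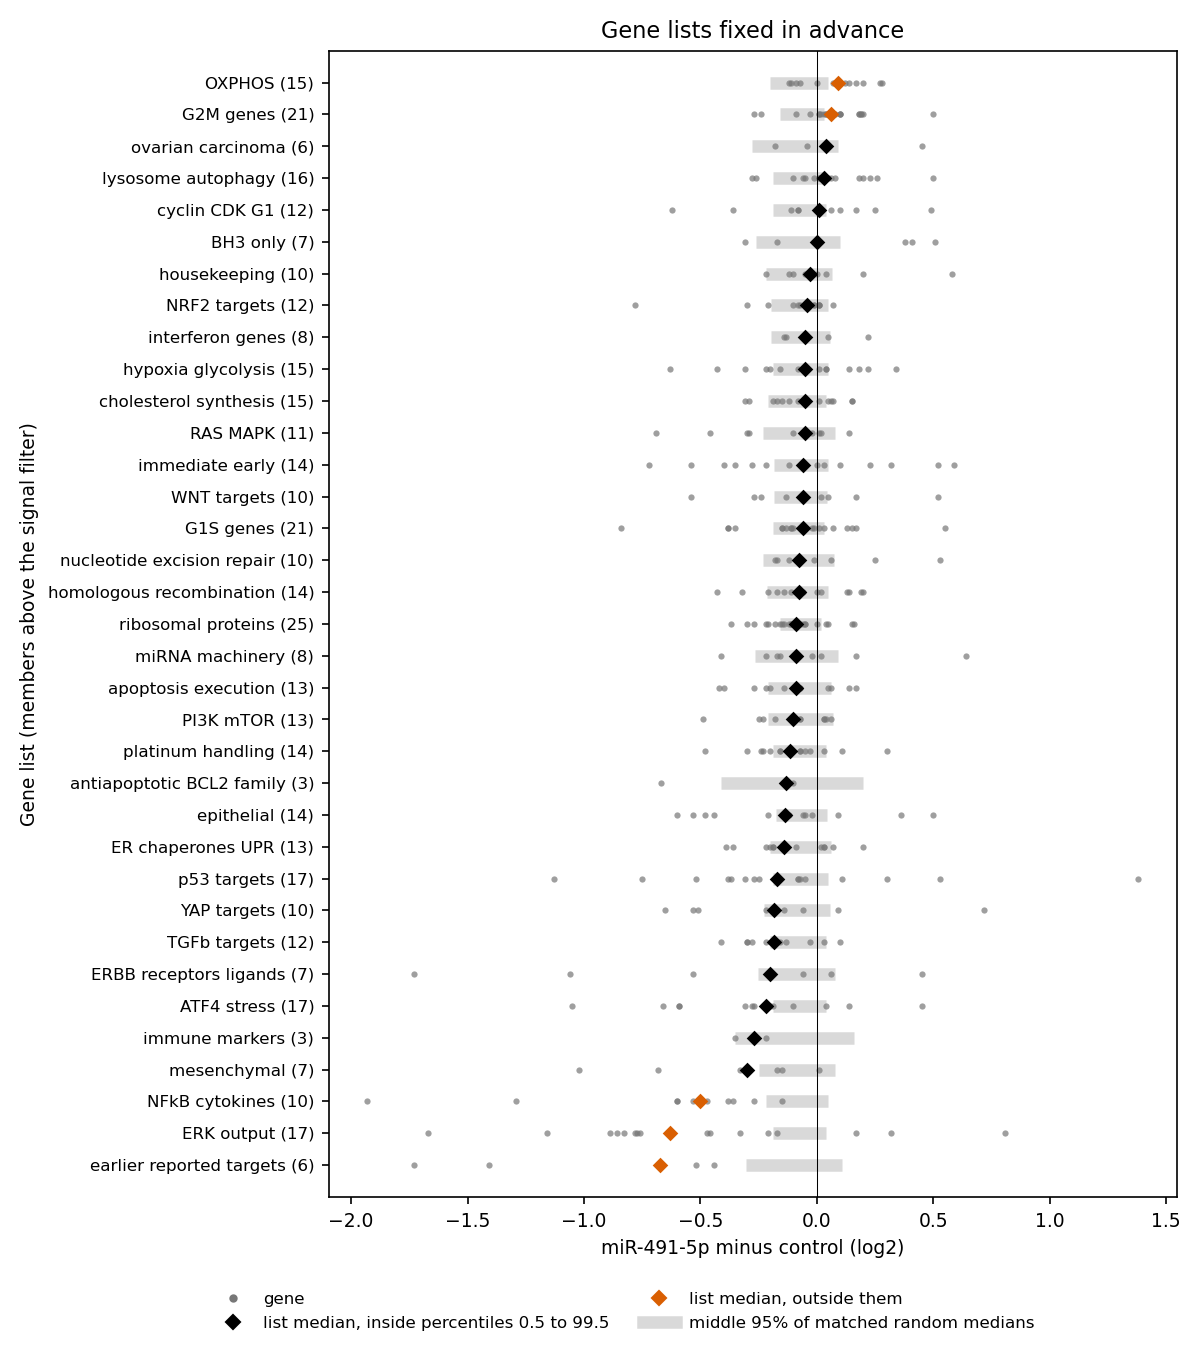
Rows are the 35 gene lists with at least 3 members above the signal filter (number in brackets), and the x axis is the miR-491-5p minus control difference (log2). Grey points are genes, diamonds list medians and grey bars the middle 95% of medians of 10000 signal-matched random sets. The earlier reported targets, ERK output and NF-κB medians lie left of their bars, at -0.68, -0.63 and -0.50, and the G2/M and OXPHOS medians lie to the right, at 0.06 and 0.09.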

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

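Of the tests reported here, those of a scaling offset, of dim genes and of immediate early genes, and the count of probe sets without a gene symbol, were chosen only after the result was seen. The median-centred counts behind the scaling test were planned, and only their use as that test came after. The rule that immediate early members going both ways decide nothing was added after their values were seen.

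The gene comparison left out probe sets without a gene symbol. Among 19031 of them above the filter, 47 were at least 2-fold higher and 133 at least 2-fold lower on the miR-491-5p array, so 26.1% of those past 2-fold were higher, against 6.03% among named genes. They were singled out as signal above the control array outside the gene comparison. The highest, TC15001009.hg.1, read 7.10 against 3.34 (difference 3.76). Its control value lay far below the filter (5.55), and signal over background is unknown, so the size of this difference may not be a measured change. With both arrays above the filter, 38 were higher and 110 lower, and the highest, TCUn_gl000223000003.hg.1, read 9.18 against 6.10 (3.08). The lowest, TC17002651.hg.1, read 7.82 against 10.39 (-2.57).

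The excess of lower genes (109 against 7) was set against 3 technical explanations. The intervals given here treat genes as independent of each other. They hold for these 2 arrays only and carry no error between cultures. After centring the differences on their median, 81 genes were lower and 13 higher, so 86.2% were lower (exact 95% interval 77.5 to 92.4), which argues against a scaling offset as the whole cause. Of the 109 lower genes, 4.59% lay in the dimmest tertile of genes (interval 1.51 to 10.4), which argues against noise of dim genes. Chromosomes 16, 17, 19 and 22, which are gene-dense and GC-rich, held 38 of the lower genes, against a mean of 21.0 and a maximum of 34 in 1000 signal-matched random sets. The lower share was 1.73% on chromosome 16, 1.27% on 17 and 1.24% on 19, against 0.622% outside the 4, while chromosome 22 held 2 lower genes of 357 (0.560%). Among single autosomes outside the 4, the share ran from 0% on chromosomes 18 and 21 to 1.52% on 20 (6 of 394). Chromosome 19 taken alone held 13, inside its random range (mean 7.0, maximum 15). On the other chromosomes 90.9% of genes past 2-fold were still lower (70 against 7, interval 82.2 to 96.3) and the median difference was -0.07 in both sets. An effect of GC content limited to some transcripts stays open, as do direct repression through seed-matched sites, which needs transcript sequences, and any difference between the 2 cultures, which 1 array per group cannot separate from the treatment.

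For the lower ERK output genes, a general loss of induced, short-lived transcripts was tested through the immediate early list. Many immediate early genes also respond to ERK signalling, so this list cannot separate such a loss from lower ERK signalling. That list ranked at percentile 53.89, but its members went both ways, with 7 of 14 below 0 (KLF6 -0.72, MYC -0.54) and 6 above (FOS 0.59, FOSB 0.52), so the median near 0 does not decide and this explanation stays open. A few members alone were tested by leaving out the 3 lowest. The median of the rest was -0.47, at percentile 0 of random sets trimmed the same way. A median is hardly moved by 3 extreme members, so the trimming adds little to the untrimmed median of -0.63. Lower receptor input, with EGFR itself at -1.73, remains a candidate explanation, but not all values go with it. Of the 17 ERK output genes, 14 were below 0 and 3 above, EGR1 and CCND1 among them, and FOS and FOSB were higher. The ERBB receptors and ligands ranked at percentile 6.96, inside the bounds. Direct repression of list members through seed-matched sites stays open too. The 2 arrays cannot separate these explanations from other differences between the cultures.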

How the results depend on the processing

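With 1 array per group, no replicate could be left out. No paired analysis was possible because each group holds 1 array. The seed-site comparison and its alternatives were not run. Median centring gave 81 lower and 13 higher genes, and the loess correction 76 lower and 13 higher. All 81 and all 76 were among the 109, and both settings kept the 7 higher genes. Centring raised every difference by 0.07 and loess those of named genes by 0.045 to 0.103, so this overlap was largely fixed by arithmetic. At 1.5-fold, 521 were lower and 97 higher, and at 3-fold 19 and 0. Without a filter, with both arrays above it, or with mean probe sets, 107 to 109 were lower and 7 higher. In probe sets without a symbol, an alternative chosen after seeing the data, 133 were lower and 47 higher. Of 210 list comparisons, 209 kept their side of the percentile bounds. The exception was the ATF4 stress list (median -0.22), which passed the lower bound at percentile 0.415 with unmatched random sets. The comparisons under centring could not differ, because a constant shift moves no list's rank beyond the random draw. Differences of named genes shifted by 0.07 under centring, 0.045 to 0.103 under loess and -0.01 to 0.22 with mean probe sets, the largest in BCL2L11 (0.63). None past 2-fold changed sign, which shifts this small could not bring about. Under both scalings EREG, CHAC1 and SNAI1 fell below 2-fold, and KIF4A, HIPK1, MAP2K6, NARS2, MNAT1 and YWHAB passed it. Depth does not apply to these arrays, and signal over background is unknown.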

Other observations

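The genes in this paragraph were chosen after their values were seen, and most lie outside the lists fixed in advance. In the protein phosphatase 6 holoenzyme, the regulatory subunits ANKRD52 (-1.78) and PPP6R1 (-1.31) were at least 2-fold lower, while the catalytic subunit PPP6C read 0.36, PPP6R2 0.22, PPP6R3 0.02 and ANKRD28 -0.11. Of the TGF-beta receptors, TGFBR2 differed by -1.27 and TGFBR1 by 0.06. Among integrins, ITGA3 differed by -1.24, ITGB8 by -0.78, ITGA5 by -0.68, ITGB3 by -0.54, ITGAV by -0.42 and ITGB4 by -0.38, while ITGB1 (-0.13), ITGA2 (-0.06), ITGA6 (-0.05), ITGB5 (0.08) and ITGA1 (0.15) differed less. Both chains of the large neutral amino acid transporter were lower, SLC7A5 at 14.03 against 15.20 and SLC3A2 at 11.55 against 12.21. The neural adhesion molecule L1CAM (-1.40) and the keratin KRT80 (-1.32) were lower, whereas the desmosomal genes DSC2 (1.13), PKP2 (0.89) and DSG2 (0.38) were higher, with DSP at -0.02 and JUP at 0.13. The long non-coding RNAs CCAT1 (8.05 against 9.52) and LINC00941 (7.68 against 8.91) were lower, and MALAT1 read 16.05 against 16.06.

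CDH5, an endothelial cadherin, read 13.23 on the control array of this carcinoma line, while the endothelial genes KDR (4.57), TEK (4.90), TIE1 (5.19), EMCN (5.10) and ERG (4.66) were below the filter there and CLDN5 (6.58) was above it.

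SESN3 (1.02), TP53INP1 (1.38) and KLHL24 (0.88), reported FOXO targets, were higher on the miR-491-5p array, as were ERBB3 (0.45), CDKN1B (0.49) and BCL2L11 (0.41). Growth factor signalling through AKT normally restrains FOXO activity. A hypothesis of higher FOXO activity was tested on 22 other genes, listed as FOXO targets before their values were looked at. The list held FOXO1, FOXO3 and FOXO4 themselves, whose own transcripts are a less direct readout of FOXO activity. No rank was computed without them. Of the 19 above the filter, 13 were above 0 and 6 below. Their median of 0.05 ranked at percentile 98.7 of matched random sets (98.6 to 99.6 over 5 processing alternatives), past the limit of 95 set beforehand for this list. The median itself was 0.12 after median centring and 0.12 after the loess correction. The value did not reach the outer 0.5 percentiles required of the other lists, and 1 of the 5 alternatives (the stricter filter) did, so by that bound the list did not stand apart. FOXO1 (0.43), PINK1 (0.41), FOXO3 (0.36) and CAT (0.32) were the highest, and GADD45A (-0.72), IRS2 (-0.56) and FBXO32 (-0.45) went against it. The result is consistent with the hypothesis, but the differences are small and rest on 1 array per group.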
